A study of Homo sapiens with 6 samples.

How the data were processed

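RNA from 6 samples labelled A549, a human lung adenocarcinoma cell line, was sequenced after transfection with an siRNA against SF3B4 or with a scramble control siRNA, 3 libraries per group. An siRNA is a short double-stranded RNA whose guide strand directs cleavage of a matching transcript. Groups and replicate numbers were taken from the sample titles. The titles call the replicates biological but do not say whether they were separate cultures or days, so p-values measure only the spread between these samples. The genotype labels of SF3B4 siRNA replicates 2 and 3 name SF3B5 and SF3B6, while their titles and treatment labels name SF3B4. The titles were followed. The names under which the tables were deposited carry the name of another lung cancer line, H1650, while the labels name A549 throughout. The libraries are therefore called libraries labelled A549.

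The authors deposited 1 FPKM value per gene and library (fragments scaled by transcript length and by the total of mapped fragments), for 50868 Ensembl gene identifiers. HISAT2 2.0.4, StringTie 1.3.0 and the build GRCh38 are named in the submitters' processing notes, without their roles or order. The RNA was total RNA and the libraries were made with a kit for Illumina sequencing, per the labels' protocols. The gene annotation, the strand setting, read layout, transcript selection, siRNA sequences, dose and time after transfection are not given in the sources used here. FPKM values are not counts, so no count test was run. In genes with a single exon, the product of FPKM and exonic length moved in steps of 54 to 57.1, the size of 1 fragment. Of the 2179 to 2301 low values per library (up to 20 fragments), 99.1% to 99.5% lay within 0.02 of a whole number of fragments. The steps imply 17511126 to 18529764 fragments per library as the total by which the authors scaled; a further scaling factor would be contained in it. At 1 FPKM, a gene of the median exonic length of 4128 bases then held 72.3 to 76.5 fragments, and counting error alone gave a coefficient of variation of at most 11.8%. Such figures cover counting error only.

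Symbols came from a table of gene names for 49659 of the identifiers, and 50111 were found in GENCODE 29 (GRCh38), which supplied positions, gene types, lengths and 3' UTRs. That annotation may differ from the one the authors used. Genes with FPKM of at least 1 in at least 3 of the 6 libraries were tested, 9685 in all. The test was limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with intensity trend and robust option, two-sided) on log2(FPKM + 0.1), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. An adjusted p of a gene comes from this limma fit unless an alternative is named. Fold changes are on the log2(FPKM + 0.1) scale, which understates changes of low genes, and calls of 2-fold or more needed a log2 fold change of at least 1 in size. Levels are means ± SD of FPKM over 3 libraries per group.

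Before the data were examined, 41 gene lists were fixed. The 36 lists with at least 5 tested members, leaving out a list of genes typical of A549, entered camera with its preset correlation of 0.01, adjusted over the lists. Camera asks whether a list's members moved relative to all other genes. It was repeated with the correlation estimated for each list. That version also uses the residual degrees of freedom of the fit, few with 6 libraries, so the same statistic gives a larger p. A rotation test, fry, asked whether members moved one way on balance without reference to other genes. The rule for named genes was also fixed beforehand: 4 single genes, of which SF3B4, SF3B5 and SF3B6 are reported; the 10 largest rises and 10 largest falls past the threshold with mean FPKM of at least 5, no overlap between groups and a proper symbol; all tested SF3b and SF3a members; and up to 4 members of each other list, those with the largest change past the threshold in the direction of the list's call, or either direction without a call (up to 2 with the smallest p where none passed). Not every gene the rule allows is named. Any other gene is said to have been chosen after its values were seen.

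On simulated data for this comparison with 9408 tested genes, the fit recovered 48 of 63 genes changed by 1.5-fold, 66 of 66 changed by 2-fold and 62 of 63 changed by 4-fold, with 17 false calls, 8.81% of all calls. Camera recovered the planted list and called 0 of 20 unchanged lists. Unlike the data, few genes were changed, in balanced directions, and all shared the same median dispersion. Camera ran there without the intensity trend used on the data. These rates are therefore those of the simulation and may differ in the data. Genes were simulated independently of each other, so this does not show how camera behaves for lists with correlated members. In the data, the estimated correlation reached 0.60, in the mitochondrially encoded list. SF3B4, SF3B5 and SF3B6 were also compared with an exact two-sided permutation test of FPKM, which cannot go below 0.1 with 3 against 3.

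After the largest falls had been seen, the presence of each 7-mer in the 3' UTR of the longest coding transcript was related to log2 fold change in 8361 protein-coding genes. Each of the 16083 7-mers with at least 50 carriers had its own regression, adjusted for UTR length and GC content, and 100 permutations gave the distribution of the most extreme statistic. In simulated values with a fall of 0.3 given to the carriers of 1 7-mer, that 7-mer ranked first in 5 of 5 runs. Genes without an annotated 3' UTR were not searched. Figures and this regression used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

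The alternatives were pseudocounts of 1 and 0.01, no filter, a mean FPKM of at least 5, rescaling to TPM, upper-quartile and median-ratio scaling of FPKM, quantile normalization, a fit without intensity trend and robust option, array weights, a 1.2-fold minimum inside the test, the replicate number as a block and the omission of each library. The omission of genes that carry a 7-mer site or were not searched was added after the data were seen. Reads shared with processed pseudogenes could not be separated in FPKM, and strand was unknown, so the text marks named genes that have a pseudogene at a comparable level, or another gene over more than 20% of their exonic length.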

Results

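The data were FPKM values for 50868 genes in 6 RNA-seq libraries labelled A549, 3 from cells given a scramble control siRNA and 3 from cells given an siRNA against SF3B4. SF3B4 encodes a subunit of SF3b, the part of the U2 small nuclear ribonucleoprotein that contacts the branch point of introns during splicing. The implied depth was 18235260, 17751895 and 18167086 fragments in control replicates 1 to 3 and 17511126, 18116509 and 18529764 fragments in SF3B4 siRNA replicates 1 to 3. Of all listed genes, 9327 to 9678 per library reached an FPKM of 1. The design asks how transcript levels differed after depletion of SF3B4.

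SF3B4 itself fell to 22.6% of its control level. The gene (ENSG00000143368, GRCh38 chromosome 1, 149923317 to 149928344) stood at 88.6, 92.0 and 93.8 FPKM in the control libraries and at 22, 17.7 and 22.3 FPKM in the SF3B4 siRNA libraries. The log2 fold change was -2.15 with a standard error of 0.10 (limma adjusted p = 8.8e-05). SF3B5, which encodes another small SF3b subunit (chromosome 6, 144094881 to 144095573), also fell, from 426 ± 30.5 to 199 ± 8.96 FPKM (SD, n = 3 each), a log2 fold change of -1.10 ± 0.07 (SE, limma adjusted p = 9.6e-05). SF3B6 was at 45.9 ± 3.11 and 41.5 ± 2.2 FPKM, a difference that did not pass the test (adjusted p = 0.18). The exact two-sided permutation test gave p = 0.1 for SF3B4 and SF3B5, the smallest it allows, and p = 0.2 for SF3B6. The SF3B4 siRNA replicates 2 and 3, whose genotype labels name SF3B5 and SF3B6, had SF3B5 levels of 189 and 207 FPKM against 201 FPKM in replicate 1, and SF3B6 levels of 43.3 and 42.2 FPKM against 39.1 FPKM. A processed pseudogene, SF3B4P1, was listed at a mean of 1.82 FPKM over the 6 libraries, beside 56.1 FPKM for SF3B4.

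**Figure D1:**
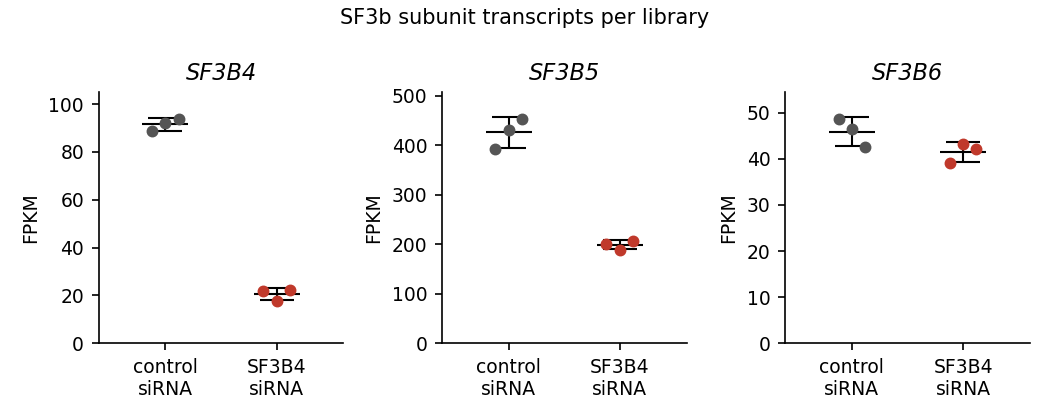
FPKM of SF3B4, SF3B5 and SF3B6 (vertical axes) in each library, with grey points for control siRNA and red points for SF3B4 siRNA; wide bars are means and the outer bars are 1 SD over 3 libraries. SF3B4 lay at 17.7 to 22.3 FPKM after SF3B4 siRNA against 88.6 to 93.8 FPKM in controls, and the SF3B6 groups lay within 39.1 and 48.7 FPKM.

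Of the other SF3b and SF3a subunits, PHF5A rose from 37.9 ± 2.48 to 50.3 ± 1.63 FPKM and SF3B2 from 17.4 ± 0.714 to 20.4 ± 0.511 FPKM. SF3A2 fell from 12 ± 0.417 to 9.34 ± 0.385 FPKM, SF3A3 from 14.6 ± 1.1 to 11.1 ± 0.775 FPKM and SF3A1 from 18 ± 0.749 to 15.5 ± 0.61 FPKM. SF3B1 (5.31 and 5.85 FPKM), SF3B3 (57.6 and 56.2 FPKM) and DDX42 (2.05 and 1.98 FPKM) did not pass the test. In all, 2 of the 10 tested partners rose and 4 fell, the same numbers when adjusted over the list alone, and the list as a whole was not called by camera (adjusted p = 0.40). The calls of SF3B2 and SF3A1 were lost in 9 and 13 of 18 alternatives (adjusted p over all of them 0.011 to 1.0 and 0.024 to 1.0). Both were lost without any 1 of the SF3B4 siRNA replicates and without control replicate 2 or 3 (adjusted p 0.057 to 0.10 for the SF3B2 log2 fold change, 0.078 to 0.16 for the SF3A1 log2 fold change). Both were also lost without the filter, without intensity trend and robust option, with the replicate block and with a minimum fold change of 1.2 in the test, and SF3A1 with each of the other scalings.

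Across the transcriptome, 1546 genes were higher and 1752 lower after SF3B4 siRNA, 34.1% of the 9685 tested. Which direction had more calls depended on the scaling, with 1648 higher and 1629 lower after rescaling to TPM and 1738 higher and 1636 lower after quantile normalization. Falls outnumbered rises among the larger changes, with 286 genes lower and 106 higher by 2-fold or more. Among genes with a mean FPKM of at least 5 and no overlap between groups, the largest rises included LRG1, a secreted leucine-rich glycoprotein (2.95 ± 0.381 to 11.7 ± 1.46 FPKM), TMEM140 (3.19 ± 0.442 to 11.5 ± 1.55), PIR, which encodes pirin (3.01 ± 0.223 to 9 ± 0.724), the interferon-inducible GTPase gene GBP2 (2.94 ± 0.0816 to 8 ± 1.16) and the desmosomal cadherin gene DSG3 (3.49 ± 0.629 to 9 ± 1.59). HSPB8, a small heat shock protein gene, rose from 12.1 ± 0.898 to 30.2 ± 0.182 FPKM. CEMIP2, HTATIP2 and OGFR were also among the 10 largest rises, with log2 fold changes of 1.3, 1.29 and 1.24. Among the same genes, the largest fall was that of POLE4, an accessory subunit of DNA polymerase epsilon (38.4 ± 5 to 6.78 ± 1.66 FPKM, log2 fold change -2.51), ahead of SF3B4. It was followed by CAP1, an actin regulator (30.6 ± 3.27 to 7.68 ± 1.69), the lysosomal sialidase gene NEU1 (12.3 ± 0.506 to 3.13 ± 0.452), LSM4, a component of U6 small nuclear ribonucleoprotein (67.4 ± 7.59 to 17.5 ± 3.09), HSPA2 (44.9 ± 4.86 to 11.9 ± 1.64) and the tetraspanin gene CD81 (21 ± 1.3 to 5.58 ± 0.108). B4GALT5, OAT and F2RL1 fell with log2 fold changes of -1.88, -1.84 and -1.84. Adjusted p of these genes was at most 0.0011. The exons of CAP1 overlapped those of PPT1 on the other strand over 31.2% of their length, and those of TMEM140 overlapped CYREN over 22.7%, so both values are uncertain. Groups did not overlap in 49.5% of tested genes, where chance gives 10%. The first principal component held 55.9% of the variance and separated the groups, and correlations between libraries were 0.980 to 0.984 within groups and 0.955 to 0.965 between them.

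Part of the genes that fell had a short sequence in common in their 3' UTRs. GCCTTCA was the 7-mer most strongly tied to falls (slope -0.37 per carrier on the log2 scale, permutation p = 0.0099, the smallest that 100 permutations can give). Its 1045 carriers had a median log2 fold change of -0.24, against 0.02 in the other genes. The overlapping 7-mers TGCCTTC and CCTTCAA came next. Of the 248 searched genes that fell by 2-fold or more, 147 (59.3%) carried GCCTTCA or CCTTCAA, against 17.6% of the others. Of all 1562 searched genes that fell, 532 (34.1%) carried either, against 15.4% of the others. These shares describe the genes from which the 7-mers were picked and are no separate test. Among genes higher by 2-fold or more, 4 of 83 carried either. The median was -0.34 in 225 genes with both 7-mers overlapping as 8 bases, -0.22 in 820 other genes with GCCTTCA, -0.06 in 532 genes with CCTTCAA but not GCCTTCA and 0.03 in 5193 genes with none of these and no 6-mer CCTTCA. The medians of the first 3 classes were below 0 in each SF3B4 siRNA library. POLE4, CAP1, NEU1, LSM4, CD81, B4GALT5, F2RL1 and SF3B5 carried GCCTTCA in the 3' UTR. SF3B4 did not, but GCCTTCA occurs once in its longer transcript, in the coding part of exon 3 of 6 (GRCh38 chromosome 1, 149926547 to 149926553, minus strand). The search was chosen after the largest falls were seen, and in what follows a site, or 7-mer site, is GCCTTCA or CCTTCAA in a 3' UTR. Of the 4 fallen SF3b and SF3a partners, 2 carried a site, SF3B5 and SF3A3, the latter with CCTTCAA. Of the 8 tested partners without a site, 2 fell and 2 rose.

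**Figure D2:**
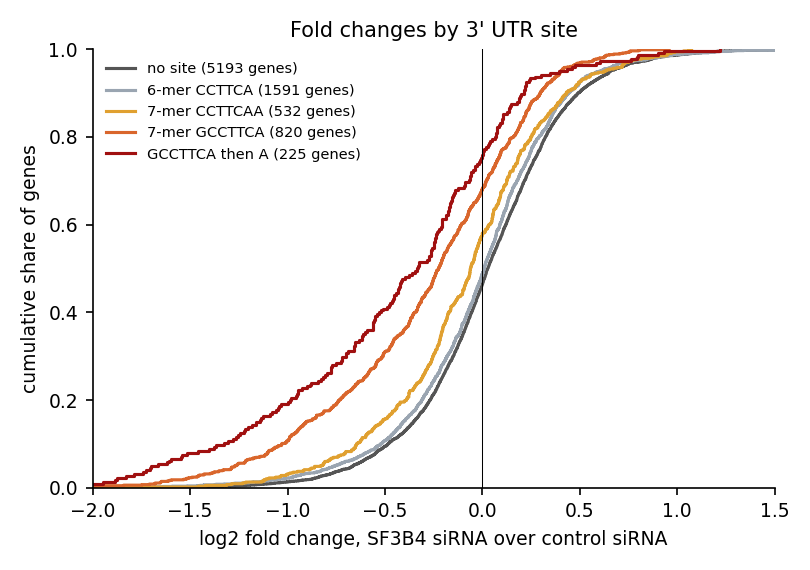
Cumulative share of genes (vertical axis) against log2 fold change, SF3B4 siRNA over control siRNA (horizontal axis), for classes of 3' UTR site; each line is 1 class, with its number of genes in the key. The 225 genes with the 8-base site lie furthest left, with a median of -0.34 against 0.03 for the 5193 genes with no site.

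DNA replication and cell division genes fell as groups. Of 40 tested DNA replication and G1/S genes, 32 fell and 0 rose (35 lower adjusted over the list alone), with a median log2 fold change of -0.60. Examples were the primase subunit PRIM1 (1.92 ± 0.422 to 0.704 ± 0.148 FPKM), GINS1 of the replicative helicase (10.9 ± 1.52 to 4.45 ± 0.663), the clamp loader subunit RFC3 (2.4 ± 0.694 to 0.988 ± 0.257) and the origin licensing factor CDC6 (10.5 ± 1.25 to 4.75 ± 0.803). Camera called the list (adjusted p = 1.2e-10), and the call was lost at adjusted p = 0.34 with an estimated correlation. Of 37 mitotic genes, 27 fell and 0 rose (29 lower adjusted over the list alone), with a median of -0.45. They included the spindle checkpoint gene MAD2L1 (4.33 ± 0.361 to 1.55 ± 0.219), CDCA3 (5.25 ± 0.31 to 2.2 ± 0.0898), the kinase gene AURKB (13.9 ± 0.774 to 7.61 ± 1.11) and the centromere chaperone gene HJURP (5.33 ± 0.62 to 2.88 ± 0.155). Here camera gave adjusted p = 1.9e-09, and adjusted p = 0.34 with an estimated correlation. A pseudogene, MAD2L1P1, was listed at 1.72 FPKM beside 2.94 FPKM for MAD2L1, which is uncertain for that reason. The 7-mer site was carried by 5 of the 32 fallen replication genes, PRIM1 among them, and by 0 of the 27 fallen mitotic genes.

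Homologous recombination and Fanconi genes fell in 10 of 17 cases, with 0 rises and the same counts adjusted over the list alone (camera adjusted p = 0.00091, adjusted p = 0.22 with an estimated correlation). FANCC fell from 2.18 ± 0.265 to 0.825 ± 0.0388 FPKM and EXO1 from 1.92 ± 0.384 to 1.09 ± 0.0639 FPKM. RAD54L (5.21 ± 0.341 to 2.54 ± 0.182) and XRCC3 (5.18 ± 0.161 to 2.53 ± 0.355) fell too, but overlap LRRC41 and KLC1 on the other strand over 25.1% and 76.7% of their exons. FANCC was the 1 fallen member with a 7-mer site. Among G1 cyclins and CDK inhibitors, cyclin D1 (CCND1) fell from 13.8 ± 1.08 to 4.96 ± 0.744 FPKM, CDK2 from 5.19 ± 0.525 to 1.88 ± 0.338 and CDK4 from 28.7 ± 1.49 to 19.7 ± 1.87, 3 of 9 tested (3 adjusted over the list alone), none with a site. The G1 list was not called (adjusted p = 0.22), and CDK4 overlaps TSPAN31 over 43.2% of its exons.

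Camera at its preset correlation called the AP-1, YAP and TEAD, TGF-beta and SMAD, and EGFR family lists lower. AP-1 and immediate early genes fell in 10 of 19 cases and rose in 1 (the same counts adjusted over the list alone). The AP-1 subunit gene FOSL1 was at 4.12 ± 0.685 and 1.35 ± 0.176 FPKM. The ETS factor genes ETV5 and ETV4 were at 3.62 ± 0.102 and 1.27 ± 0.212, and 1.53 ± 0.241 and 0.495 ± 0.0476. The list passed camera at adjusted p = 0.0022, not with an estimated correlation (adjusted p = 0.20) nor at a mean FPKM of at least 5 (adjusted p = 0.17; range over the alternatives 0.00016 to 0.2). YAP and TEAD targets fell in 9 of 16 cases (11 adjusted over the list alone, 0 rises). CCN2 was at 3.03 ± 0.256 and 0.655 ± 0.119 FPKM, FJX1 at 13.8 ± 0.161 and 6.38 ± 0.731, and AMOTL2 at 6.76 ± 0.778 and 3.26 ± 0.518 (camera adjusted p = 0.00023, adjusted p = 0.34 with an estimated correlation). TGF-beta and SMAD targets fell in 6 of 10 cases (8 adjusted over the list alone, 0 rises), again with CCN2, and with SMAD6 at 4.61 ± 0.0666 and 2.49 ± 0.202 FPKM. That list gave camera adjusted p = 0.0013, adjusted p = 0.20 with an estimated correlation, and 0.076 at a mean FPKM of at least 5 (range 7.4e-05 to 0.2). The EGFR family and ligands list had 7 of 12 members lower (8 adjusted over the list alone, 0 rises). They included the receptor genes ERBB2 (18.9 ± 0.818 to 11.5 ± 0.597) and FGFR1 (1.46 ± 0.0413 to 0.678 ± 0.0912) and the ligand gene HBEGF (1.05 ± 0.0453 to 0.482 ± 0.0601). Camera gave adjusted p = 0.0070, and adjusted p = 0.35 with an estimated correlation. Sites were carried by 2 of 10 fallen AP-1 genes, 4 of 9 YAP targets, 0 of 6 TGF-beta targets and 5 of 7 EGFR family genes. Of the genes named in this paragraph, FOSL1, FGFR1 and HBEGF carried a site and the others did not. Without site carriers the EGFR family list lost its call (camera adjusted p = 0.16, range 0.0013 to 0.35).

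Mesenchymal and epithelial genes did not pass as lists (camera adjusted p = 0.10 and 0.24), though at a mean FPKM of at least 5 the epithelial list did (adjusted p = 0.045). In fry, which does not compare a list with other genes, both passed (adjusted p = 0.0040 and 0.0029). The integrin gene ITGB1 fell from 33.1 ± 1.83 to 11.6 ± 0.966 FPKM, vimentin (VIM) from 3.46 ± 0.702 to 1.54 ± 0.121, MMP2 from 75.9 ± 5.5 to 50.7 ± 2.38 and SPARC from 90.2 ± 3.64 to 61.6 ± 2.93. These were 4 of 7 mesenchymal falls among 15 tested genes, beside 3 rises (9 and 3 adjusted over the list alone), and 5 of the 7 carried a site. ITGB1 is uncertain, since its pseudogene ITGB1P1 was listed at 111 FPKM. Among 23 epithelial genes, 7 rose and 2 fell (7 and 3 adjusted over the list alone). E-cadherin (CDH1) was at 41.2 ± 7.75 and 75 ± 12.1 FPKM, the mucin gene MUC1 at 4.39 ± 0.46 and 8.17 ± 0.687, and ELF3 at 22.4 ± 0.508 and 33.9 ± 0.426. Neither epithelial fall carried a site.

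Proteasome subunits and cholesterol synthesis genes rose. Of 31 proteasome genes, 22 rose and 2 fell (24 and 2 adjusted over the list alone). PSMC4 was at 67.3 ± 4.14 and 121 ± 3.45 FPKM, PSMD4 at 38.7 ± 0.874 and 67.7 ± 2.31, and PSMB7 at 123 ± 4.61 and 197 ± 10.4. The median log2 fold change was 0.49 (camera adjusted p = 1.1e-07, adjusted p = 0.22 with an estimated correlation). Both falls, PSMB5 (log2 fold change -1.70) and PSMD14 (-0.92), named after their values were seen, carried a site. Of 21 cholesterol synthesis genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone). Among them were LSS (9.45 ± 0.476 to 17.7 ± 0.88) and MVD (10.5 ± 0.532 to 19.1 ± 1.1). Here camera adjusted p was 1.8e-05, and adjusted p = 0.20 with an estimated correlation. LSS rose although it carries the 8-base site, and the 1 fallen member carries a site. Fatty acid synthesis genes were not called (3 of 14 higher, 1 lower, 3 and 2 adjusted over the list alone, adjusted p = 0.57), but FASN rose from 71.2 ± 2.52 to 129 ± 2.64 FPKM and FADS1 fell from 3.99 ± 0.425 to 2.17 ± 0.218 FPKM.

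Nuclear genes of respiratory complex I rose in 12 of 35 cases and fell in 2 (14 and 2 adjusted over the list alone). NDUFA8 was at 90 ± 5.4 and 141 ± 4.37 FPKM (camera adjusted p = 0.00093, adjusted p = 0.20 with an estimated correlation). Transcripts encoded in mitochondrial DNA went the other way, with 7 of 13 lower and 0 higher (10 lower adjusted over the list alone), a median of -0.27, and MT-ND3 at 1706 ± 166 and 1258 ± 43.6 FPKM. That list gave camera adjusted p = 0.0013, and adjusted p = 0.57 with an estimated correlation. Targets of NRF2, the regulator of antioxidant genes, rose in 11 of 21 cases and fell in 3 (12 and 3 adjusted over the list alone). They included PIR, AKR1B10 (0.885 ± 0.0935 to 2.16 ± 0.151) and the heme oxygenase gene HMOX1 (40.3 ± 1.75 to 69.9 ± 3.9). The NRF2 call (camera adjusted p = 0.041) was lost with an estimated correlation (adjusted p = 0.31), with quantile normalization (0.087), without SF3B4 siRNA replicate 3 (0.053) and without control replicate 2 (0.060), with a range of 0.0013 to 0.31 over the alternatives of the NRF2 target genes. Sites were carried by 2 of 3 fallen NRF2 targets and 1 of 2 fallen complex I genes, and mitochondrial transcripts were not searched.

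Among RNA processing genes outside SF3b and SF3a, core spliceosome genes went both ways, with 10 of 36 lower and 3 higher (the same counts adjusted over the list alone, camera adjusted p = 0.48). CHERP fell from 7.45 ± 0.225 to 3.61 ± 0.459 FPKM, PRPF4 from 14.7 ± 1.47 to 9.65 ± 0.798 and the polypyrimidine tract factor U2AF2 from 86.7 ± 3.38 to 61 ± 3.21. CHERP was the 1 fallen member with a site. hnRNP genes fell in 6 of 25 cases and rose in 1 (4 and 1 adjusted over the list alone). PTBP1 was at 11.7 ± 3.22 and 5.77 ± 0.742 FPKM and HNRNPAB at 26.1 ± 1.34 and 16.8 ± 1.24. PTBP1 carries a site and HNRNPAB does not. The hnRNP call (camera adjusted p = 0.032) was lost with an estimated correlation (adjusted p = 0.63), at a mean FPKM of at least 5 (0.11), without control replicate 1 (0.077), without SF3B4 siRNA replicate 2 (0.065) and without carriers of a site (0.0503), which 2 of the 6 fallen genes were. The range over its alternatives was 0.0075 to 0.63. SR protein genes (2 of 12 lower, 1 higher) and splicing kinase and speckle genes (3 of 10 lower, 1 higher) kept these counts adjusted over the list alone and were not called (adjusted p = 0.38 and 0.51). SRSF8 fell from 4.95 ± 0.552 to 3.25 ± 0.241 FPKM and carries a site, and SRRM1 fell from 3.81 ± 0.221 to 2.32 ± 0.176. snoRNA host genes (6 of 16 lower, 1 higher, the same adjusted over the list alone) gave adjusted p = 0.25, with SNHG19 at 21.9 ± 1.43 and 13.6 ± 1.54 FPKM. Nonsense-mediated decay factors had 2 of 13 lower and 1 higher (1 and 0 adjusted over the list alone, adjusted p = 0.51), with SMG5 at 37.3 ± 0.937 and 25.8 ± 1.9 FPKM.

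Ribosome biogenesis genes fell in 9 of 27 cases and rose in 1 (the same adjusted over the list alone). NOP2 was at 4.1 ± 0.517 and 2.61 ± 0.0424 FPKM and RRS1 at 15 ± 0.986 and 8.9 ± 0.89. A site was carried by 2 of the 9 fallen genes, RRS1 among them but not NOP2, and by the 1 that rose. The call (camera adjusted p = 0.016) was lost with an estimated correlation (adjusted p = 0.63), at a mean FPKM of at least 5 (0.15) and without control replicate 1 (0.060), in a range of 0.00049 to 0.63. Of 75 cytosolic ribosomal protein genes, 6 rose and 6 fell (2 and 6 adjusted over the list alone), and the list was not called (adjusted p = 0.98). RPS14, which carries a site, fell from 173 ± 3.11 to 54.1 ± 8.03 FPKM. RPL7A fell from 197 ± 5.6 to 144 ± 7.75 FPKM, but its pseudogene RPL7AP6 was listed at 471 FPKM, so its own level is uncertain.

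Of the stress and immune lists, those of interferon-stimulated genes and of autophagy and lysosome genes were called by camera at its preset correlation. Interferon-stimulated genes rose in 9 of 28 cases and fell in 1 (10 and 2 adjusted over the list alone). IFIT1 was at 8.64 ± 0.529 and 14.3 ± 3.11 FPKM and IFIT3 at 18.3 ± 1.67 and 25.7 ± 2.82. The interferon call (camera adjusted p = 0.040) was lost with an estimated correlation (adjusted p = 0.78), without SF3B4 siRNA replicate 2 (0.24), without control replicates 1 (0.15) or 3 (0.056), with quantile normalization (0.057), at a mean FPKM of at least 5 (0.18), in fry (0.26) and without carriers of a site (0.16), in a range of 0.0023 to 0.78. Autophagy and lysosome genes rose in 11 of 27 cases and fell in 1, which carries a site (12 and 3 adjusted over the list alone). The kinase gene ULK1 was at 6.07 ± 0.507 and 11.1 ± 0.741 FPKM and cathepsin L (CTSL) at 33.7 ± 6.58 and 61.7 ± 6.99. Their camera adjusted p was 0.0499, and it was over the threshold in 11 alternatives besides the estimated correlation (adjusted p = 0.34), among them without SF3B4 siRNA replicate 2 (0.10), without control replicates 1 (0.088) or 3 (0.064), in a range of 0.0048 to 0.34. NF-kB and inflammatory genes (2 of 12 higher, 3 lower, the same adjusted over the list alone, adjusted p = 0.98) included ICAM1, which rose from 0.837 ± 0.0684 to 2.15 ± 0.192 FPKM. p53 targets (1 of 18 higher, 4 lower, the same adjusted over the list alone) gave adjusted p = 0.69, with SESN2 at 12 ± 1.2 and 18.5 ± 1.85 FPKM and POLH at 3.82 ± 0.255 and 2.54 ± 0.155. Integrated stress response genes (3 of 28 higher, 7 lower, the same adjusted over the list alone, adjusted p = 0.94) included PSPH, which fell from 3.87 ± 0.328 to 2.16 ± 0.0619 FPKM, and 3 of the 7 falls carried a site.

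**Figure D3:**
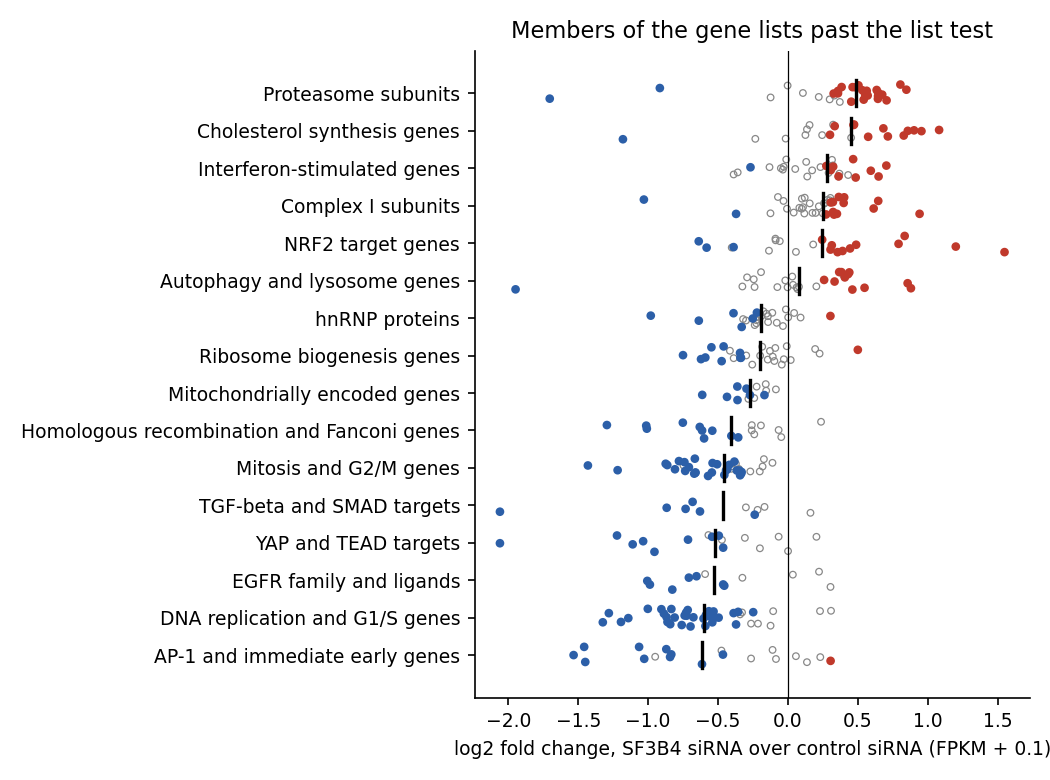
Log2 fold change of each tested member, SF3B4 siRNA over control siRNA on the log2(FPKM + 0.1) scale (horizontal axis), in the 16 lists called by camera at its preset correlation (vertical axis). Filled points passed the gene test (red higher, blue lower), open points did not and black bars are medians, which ran from -0.61 for AP-1 and immediate early genes to 0.49 for proteasome subunits.

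Camera thus called 10 lists lower and 6 higher of 36, and 0 of these 16 calls held with an estimated correlation. With an estimated correlation, where fewer degrees of freedom are used, the smallest camera adjusted p of any list was 0.20. That test therefore does not separate weaker calls from stronger ones. With the preset correlation, other groupings of the same libraries also gave up to 10 called lists. Those groupings had both treatments on each side and kept part of the treatment difference, so their calls are not a count of false calls. For 8 of the 16 lists, the estimated correlation was the 1 alternative among those run for the list that ended the call. The homologous recombination list was not run at a mean FPKM of at least 5, nor the mitochondrially encoded list without carriers of a site.

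Markers of the cell line and of other cell types were read as levels. Of 16 genes known to be high in A549, 12 had a mean FPKM under 1 over the 6 libraries, and the median of the 16 was 0.033 to 0.075 FPKM per library, against 4.67 to 4.97 FPKM for the tested genes. The aldehyde dehydrogenase gene ALDH1A1 had a mean of 0.025 FPKM and AKR1C1 0.042 FPKM, both named after their values were seen. AKR1B10 and TXNRD1 rose, though TXNRD1 lost its call in 8 of 18 alternatives, among them without any 1 of the SF3B4 siRNA replicates or without control replicate 2 or 3 (adjusted p 0.058 to 0.098 for the TXNRD1 log2 fold change). NQO1, named afterwards, averaged 167 FPKM. The count of 3 rises among the 4 tested was the same adjusted over the list alone. Of 4 tested lung lineage genes, the surfactant gene SFTPD rose from 1.34 ± 0.385 to 2.76 ± 0.338 FPKM and CAV1 fell from 16.9 ± 2.34 to 9.25 ± 0.993 FPKM (1 and 1 adjusted over the list alone). Of the leukocyte markers, HLA-DRA (0.818 ± 0.239 to 2.07 ± 0.568), CD74 (2.46 ± 0.527 to 5.63 ± 2.03) and CD14 (2.59 ± 0.239 to 5.62 ± 0.945) rose, 3 of 4 tested (3 adjusted over the list alone; without the filter CD74 had adjusted p = 0.053), while PTPRC, which encodes the pan-leukocyte antigen CD45 and was named afterwards, was listed at 0 in both groups. The fibroblast list had 1 tested gene, COL1A1, which rose from 1.33 ± 0.103 to 2.27 ± 0.0568 FPKM (1 adjusted over the list alone), and 0 endothelial markers were tested.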

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

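The omission of genes with a 7-mer site and the counts over other splits of the libraries were chosen after the results were seen; the other alternatives were planned. SF3B4 fell in every alternative that was run, with a log2 fold change of -2.21 to -2.04 and adjusted p of at most 0.00098. Counts of genes higher after SF3B4 siRNA, genes lower after SF3B4 siRNA, genes higher by 2-fold or more and genes lower by 2-fold or more stayed within 1.5 times the values reported except in the following. A pseudocount of 1 gave 36 higher and 139 lower by 2-fold or more, since it shrinks folds of low genes. No filter on low values gave 170 higher by 2-fold or more. A mean FPKM of at least 5 left 4752 genes, with 1027 higher and 940 lower, 34 and 122 by 2-fold or more. A 1.2-fold minimum inside the test left 420 higher and 693 lower. Without genes that carry a 7-mer site or lack a searched 3' UTR, 1069 genes were lower and 100 lower by 2-fold or more of 6784 tested, against 1311 and 79 higher. Leaving out 1 library at a time gave 1094 to 1492 higher and 1331 to 1604 lower, with 95 to 118 and 254 to 316 by 2-fold or more, and fewer samples lower the power of each test. Of the 3298 called genes, 2355 to 2764 kept their call and direction in these fits, and 0 reversed in any alternative. Named genes kept their direction and their side of the threshold in 2763 of 2984 values, and in 221 they lost the call. List tests kept their side of the threshold in 659 of 715 values, lost the call in 46 and gained it in 10, 9 of these in fry. Called lists were reversed in 0 values. Of the 659 values, 28 changed direction, all without a call in the main fit or the alternative. The lists that passed in fry alone or beside 1 other alternative were SF3b and SF3a (adjusted p = 0.035), splicing kinases and speckle proteins (0.038), snoRNA hosts (0.042), p53 targets (0.0029), G1 cyclins (0.016), BCL2 family and caspases (0.022), histones (0.0040), epithelial (0.0029) and mesenchymal genes (0.0040). All 16 called lists lost their call with the correlation estimated for each list. The estimate was -0.040 for the AP-1 list, -0.066 for the TGF-beta list and -0.0098 for the NRF2 list, each below the preset 0.01. For these lists, that argues against a correlation above the preset as the cause. An estimated correlation also brings camera down to the residual degrees of freedom of the fit, few with 6 libraries. For these lists, that loss remains as what ended the calls. For the other called lists, the correlation and the degrees of freedom were not separated. The replicate number did not pair the libraries (correlations of residuals -0.08, 0.02 and -0.12; 0 of 3 pairs were each other's best match). As a block it gave 1290 higher and 1537 lower, with 108 and 286 by 2-fold or more, and ended the call of the autophagy and lysosome list (adjusted p = 0.059). Rises outnumbered falls over all calls after rescaling to TPM (1648 and 1629) and quantile normalization (1738 and 1636), at a mean FPKM of at least 5 and without carriers of a site. Rescaling and quantile normalization shifted the median log2 fold change by at most 0.032. At 17511126 to 18529764 fragments per library, a gene of median exonic length at 1 FPKM has a counting error of up to 11.8%, shorter genes at that level have a larger one, and genes well below were not tested. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. Every split but the real one had both treatments on each side. Such a split keeps part of the treatment difference and adds the rest to the spread within sides. Its counts therefore do not measure false calls. For called genes, 1 of the 10 splits gave as many as the real one (3298, highest other 2). For 2-fold calls it was 1 of 10 (106 higher and 286 lower, highest other 2), and for called lists 1 of 10 (16, highest other 10).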

Other observations

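The tests of the A549 genes, of housekeeping genes and of seed matches as the whole cause of the excess of falls were chosen after their results were seen; the 7-mer, GC, length, intron and cell cycle tests were written down before they were run, though after the largest falls had been looked at. Several gene groups not described so far had no list call. Replication-dependent histone genes had 2 of 8 members higher and 0 lower (the same adjusted over the list alone, camera adjusted p = 0.10), with H2BC21 at 1.98 ± 0.426 and 5.54 ± 0.175 FPKM. BCL2 family and caspase genes had 5 of 20 higher and 2 lower (the same adjusted over the list alone, adjusted p = 0.38), with the pro-apoptotic BMF at 6.29 ± 0.365 and 10.7 ± 1.41 FPKM, and BAK1, which fell, at 34.4 ± 2.85 and 21.4 ± 0.554, beside a pseudogene, BAK1P1, at 6.94 FPKM.

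Glycolysis genes had 4 of 22 higher and 5 lower (4 and 6 adjusted over the list alone, adjusted p = 0.75), with the glucose transporter gene SLC2A3 falling from 6.49 ± 0.884 to 3.25 ± 0.424 FPKM and PFKL rising from 28.7 ± 3.12 to 49.5 ± 5.06. Hypoxia-inducible genes had 2 of 18 higher and 2 lower (1 and 2 adjusted over the list alone, adjusted p = 0.89), with ANGPTL4 at 15.2 ± 0.658 and 8.59 ± 2.49 FPKM. Endoplasmic reticulum chaperones (1 of 20 higher, 4 lower, the same adjusted over the list alone, adjusted p = 0.99) had a median of 0.03, a mean of -0.05 and a test direction down, with CANX, which carries a 7-mer site, at 15.2 ± 3.17 and 6.08 ± 2.05 FPKM. Heat shock genes (3 of 16 higher, 2 lower, 3 and 3 adjusted over the list alone, adjusted p = 0.61) had a median of 0.06, a mean of -0.08 and a test direction up, with HSPB1 at 1232 ± 52.1 and 1587 ± 126 FPKM.

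More genes fell than rose by 2-fold or more, and falls made up 73.0% of those calls. The tables argue against trends on transcript GC content and on exonic length as the cause, since falls were still 73.4% and 73.0% after each was removed, and the trends spanned 0.10 and 0.05 on the log2 scale. Loss of a splicing factor acting in proportion to intron number is argued against by a Spearman correlation of 0.0088 between log2 fold change and introns over 8473 protein-coding genes; other effects of splicing stay open. A candidate explanation is off-target pairing of the SF3B4 siRNA's seed, since the 7-mer most tied to falls, GCCTTCA, passed the permutation test (p = 0.0099, the smallest possible) and lies in the SF3B4 transcript, as 12% of the tested 7-mers do. Whether it accounts for the whole excess stays open. Falls were 56.1% of the 2-fold calls without a 7-mer site (101 of 180, exact 95% interval 48.5 to 63.5) and 62.3% in genes not searched. Among searched genes without a 7-mer site, the share was 68% with the 6-mer CCTTCA and 51.5% without it. The 7-mers were picked on these same values, which lowers the share of 56.1% by itself. Neither the siRNA sequences nor the effects of SF3B4 loss alone are known here.

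DNA replication and mitotic genes fell. Seed matches in the members' own 3' UTRs are argued against, since members without a 7-mer site had medians of -0.60 (34 genes) and -0.45 (37 genes), both below the -0.3 set beforehand as the bound. What stays open is a response to SF3B4 loss, or an indirect effect of off-target falls; neither could be tested, because no library separates the 2.

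Most genes typical of A549 lay near the floor in every library of both groups. Estimates that failed broadly and put expressed genes near 0 are argued against, since 1.40% of 143 ribosomal protein, proteasome and complex I genes (2 genes) had a mean FPKM under 1. That cutoff cannot show reads assigned to pseudogenes. RPL15, in the same set, averaged 18.6 FPKM beside 708 FPKM for its pseudogene RPL15P3. Cells of another line may be a candidate explanation, as the highest library median of the A549 genes was 0.075 FPKM, although NQO1, also on that list, averaged 167 FPKM, and a culture of A549 with an altered state was not tested. Whether the cells were H1650, the line in the names of the deposited tables, stays open.

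Among 7-mers tied to rises, CGGAGAA ranked first (199 carriers, median log2 fold change 0.19 against -0.01 in the other genes, permutation p = 0.0099, the smallest possible) and does not occur in the SF3B4 transcripts. ACCGGGT, which does, and GGAGAAA, which does not, also passed (both permutation p = 0.040, medians of carriers 0.14 and 0.02).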
